A study of Homo sapiens with 19 samples.

How the data were processed

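Gene expression was measured in 19 samples of L428, a Hodgkin lymphoma cell line, with 1 single-colour Affymetrix gene array per sample. Per the labels' protocols, L428 cells were cultured for 7 days under conventional conditions, with or without primary T cells, and with or without dexamethasone, a synthetic glucocorticoid, at 0.75 µM. Magnetic depletion of CD3-positive cells preceded RNA extraction with a Qiagen micro kit, and 50 ng of total RNA was amplified by whole-transcriptome amplification, labelled with biotin and hybridised. The labels give 4 groups, which were L428 alone (monoculture, n = 3), L428 alone with dexamethasone (n = 3), coculture with T cells (n = 7) and coculture with dexamethasone (n = 6). The sample titles of the monocultures mention a coculture while their source labels say monoculture, and the study design text describes all samples as cocultures. The source labels were followed. Arrays are named here by the number in their sample titles, and no number occurs in more than 1 group. The number follows the letters BR in the titles. Nothing in the labels says whether replicates came from separate cultures or T cell donors, so p-values measure only the spread between these samples, which may be technical.

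The authors deposited 1 table of log2 values, with 32321 probe sets and the 19 arrays, and the logarithm base is inferred from the values, which ran from 5.5 to 14 with a median of 6.6. The background correction, summarisation and normalization that produced those log2 values are not given in the sources used here. All folds therefore assume base 2. The deposited values were rounded to 1 decimal, so a group of 3 arrays can have no spread at all, and values near 6 sit close to the lowest values of the table, where differences are compressed. Array medians were 6.6 or 6.7. No pair of arrays held identical values, and 0 columns were left unmapped. The number of arrays limits the precision.

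Probe sets were named through a platform annotation table that pairs probe sets with gene symbols. It gave 1 symbol to 19158 probe sets, several to 1388 and none to 11775. Of the 19158, 19128 were found by gene identifier in a RefSeq gene table, and 0 symbols needed an update. Only probe sets with 1 symbol were named, and where a gene had several the one with the highest mean represented it in the gene lists, which left 18404 genes. FKBP5, GBP1 and the classical HLA class I heavy chain genes had no probe set of their own by this rule. Values of 24 probe sets for Y-linked genes and XIST are not reported. Control probe sets could not be told from unnamed ones, so all 32321 were tested, although the plan was to leave controls out. A fit without the 4091 probe sets numbered below the lowest named one served as an alternative.

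Differences were estimated with limma 3.58.1 in R 4.3.3. Group means of all 19 arrays were fitted together with lmFit and eBayes without a trend, and p-values were adjusted by Benjamini-Hochberg over all probe sets within a comparison at a threshold of 0.05. The model gave 5 comparisons, namely coculture against monoculture without and with dexamethasone, dexamethasone against none in monoculture and in coculture, and the difference between the dexamethasone effects (the interaction). Errors of log2 differences are standard errors (SE) of this model, except that the closing tests of marker scores, of LYZ and of array medians use the SE of the difference between the means of the groups, and errors of group means are standard deviations (SD). The genes named are, per comparison, the 10 largest rises and the 10 largest falls (5 each for the interaction) among probe sets past the threshold with 1 symbol and a mean in the higher group above the median of the table, without immunoglobulin and T cell receptor segments, plus up to 4 members of each gene list and a fixed set of markers.

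There were 24 gene lists with 507 members, 462 of them measured. The groups, the tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. List shifts were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 24 lists, and again with a correlation estimated from the data. Members past the threshold were counted after adjustment over all probe sets and after adjustment over the list alone. For 5 lists of markers of other cell types, the mean over members was taken as a score per array, and group differences were tested by exact two-sided permutation tests over all rearrangements, adjusted over 20 tests. With 3 against 3 arrays the smallest possible p is 0.1.

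Simulated data had the real mean of each probe set and 1 spread, that of the model, for all groups, with independent noise. The gene test was checked on them with 200 of 32321 probe sets changed, in 10 rounds. For coculture against monoculture without dexamethasone it recovered 82.8% of changes of 0.5 log2 and 98.2% of changes of 1 log2, with 4.80% false among the calls. For dexamethasone in monoculture, the corresponding shares were 73.3%, 96.4% and 5.76%. Dexamethasone in coculture gave 87.2%, 99.0% and 4.39%, and coculture against monoculture with dexamethasone gave 79.6%, 97.6% and 5.79%. In the real data spreads differed between groups, with CCL22 at an SD of 1.08 in coculture and 0.153 in monoculture. These shares may therefore not hold for the real calls. The same 40 simulated fits were tested with camera over 18404 genes with independent noise. Their 200 changed probe sets were drawn at random and not by list, and a mean of 0.075 lists passed per fit. Alternatives covered the variance prior, normalization, filters, array weights, marker scores as covariates, runs of consecutive sample numbers as a random block, a minimum difference of 1 log2, and leaving out each array. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.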

Results

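Expression profiles of L428 cells, a line derived from Hodgkin lymphoma, were compared after culture alone or with primary T cells, each with and without dexamethasone. The series is concerned with T cells directed at the malignant cells of this lymphoma, and the arrays address how these cells responded to T cell contact and to a glucocorticoid. The data comprised 19 arrays, namely 3 monocultures, 3 monocultures with dexamethasone, 7 cocultures and 6 cocultures with dexamethasone. Each array reported 32321 probe sets, and the arrays had medians of 6.6 or 6.7 on the log2 scale. Replicates 14 (coculture) and 15 (coculture with dexamethasone) resembled the other arrays least, with median correlations of 0.979 and 0.973, whereas the remaining arrays had values from 0.986 upward, and these 2 correlated at 0.989 with each other. Replicates 14, 15, 17 and 18, all cocultures, had the medians of 6.7. They also lay highest on the main axis of variation between arrays (31.6, 39.9, 15.2 and 14.5, next 4.11). No monoculture lay with them, so this difference enters coculture against monoculture, and no fit left all of them out.

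Coculture with T cells raised interferon-response genes, CCL22, CD274 and transcripts of other blood cells. CCL22 (probe set 7996022), a chemokine that attracts T cells bearing CCR4, was 9.17 ± 1.08 (SD, n = 7) in coculture and 6.73 ± 0.153 (n = 3) in monoculture, a rise of 2.44 ± 0.45 (SE) log2 with a limma adjusted p of 0.0231. CD274 (8154233), which encodes the checkpoint ligand PD-L1, rose by 0.73 ± 0.13 from a monoculture mean of 6.90 (adjusted p = 0.0226). The interferon-induced GTPase genes GBP4, GBP5 and MX1 rose by 1.84 ± 0.25, 1.45 ± 0.21 and 1.77 ± 0.31. LYZ (7957023), the lysozyme gene of monocytes and macrophages, showed the largest difference, 2.77 ± 0.48, from 6.13 ± 0.0577 to 8.90 ± 0.852 (adjusted p = 0.0187). CD52 (2.22 ± 0.35), ARHGDIB (2.10 ± 0.35), GMFG (1.82 ± 0.35) and the T and NK cell adhesion gene CD2 (1.51 ± 0.27) rose as well. The marker scores of T cells, NK cells and monocytes were higher in the same cocultures, by 0.35, 0.592 and 0.262 (exact permutation p = 0.0167 each). The monocyte score difference came mostly from LYZ. In total 85 probe sets were higher and 8 lower, and 27 of the rises but 0 of the falls reached 1 log2. The named falls were CNTN1 (-0.74 ± 0.14), DNER (-0.69 ± 0.08), the collagen receptor gene DDR2 (-0.66 ± 0.12), MTURN (-0.54 ± 0.07), DNAJB6 (-0.30 ± 0.06) and TSPAN12 (-0.24 ± 0.05). TNFRSF8, which encodes CD30, differed by 0.13 ± 0.09 and CCL17 by -0.12 ± 0.35 (0.10 without coculture replicate 14), neither past the threshold (adjusted p = 0.916 and 0.996). The CCL17 difference ran from -0.758 to 0.367 with marker scores as covariates. Leaving out monoculture replicate 12, 19 or 31 reduced the 93 probe sets to 2, 11 or 9, and without coculture replicate 17 or 27 there were 55 or 140. With the T cell marker score as a covariate, 0 passed in limma and 1723 had an unadjusted p under 0.05, and with the monocyte and macrophage score 2 passed. The CCL22 rise was 2.13 (SE 0.71) with the T cell score. Over the 43 genes of the interferon lists the median rise was 0.843 with that score and 0.848 without. The median of the SEs of these single genes was 0.258 with the score and 0.164 without.

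**Figure D1:**
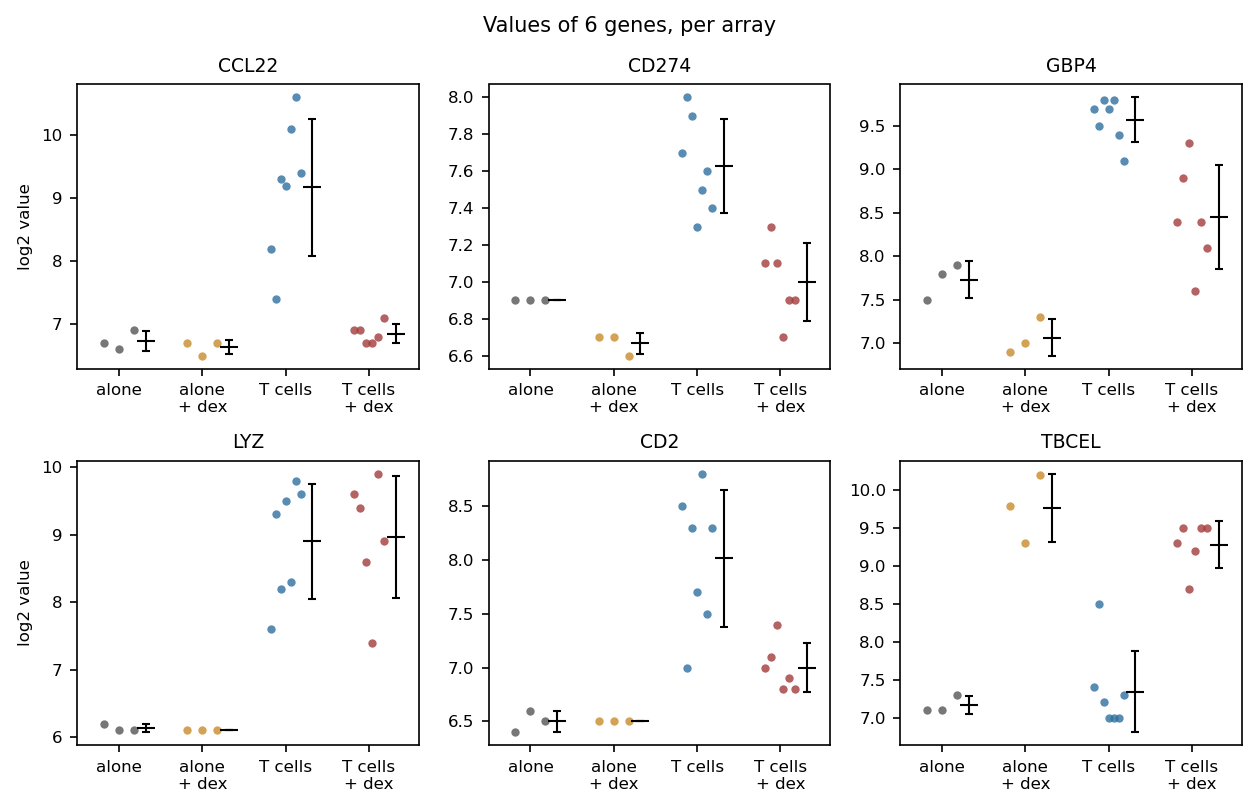
Log2 values of CCL22, CD274, GBP4, LYZ, CD2 and TBCEL on each array (points) of L428 cells alone or with T cells, without or with dexamethasone (dex), and the mean ± SD of each group (black, n = 3, 3, 7 and 6). All 7 cocultures without dexamethasone lay at 7.4 or above for CCL22, against at most 6.9 in monoculture, and the coculture array at 8.5 for TBCEL is replicate 14.

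The interferon lists carried the strongest shift in coculture without dexamethasone, on the arrays whose T cell marker score was 0.35 higher. Of 28 measured type I interferon response genes 17 rose, and 26 rose when adjusted over the list alone, with a median difference of 0.86 (camera adjusted p = 2.96e-50). DTX3L (1.43 ± 0.16), EPSTI1 (0.88 ± 0.13), the antiviral ADP-ribosylation gene PARP9 (1.72 ± 0.25) and the viral RNA sensor gene IFIH1 (0.59 ± 0.09) were among the rises. Of 15 interferon gamma response genes 5 rose, and 13 adjusted over the list alone, with a median of 0.66, including the transcription factor gene IRF1 (1.28 ± 0.19) and the aminopeptidase gene LAP3 (0.89 ± 0.14). Among 14 genes of MHC class I antigen presentation, TAP1, a subunit of the peptide transporter, rose by 0.96 ± 0.14, and 10 were higher adjusted over the list alone (median 0.40). In the list of costimulation, checkpoint and adhesion ligands, 3 of 31 rose, namely CD274, CD48 (1.17 ± 0.23) and TNFSF10 (0.62 ± 0.12), or 4 adjusted over the list alone. Cytokines and chemokines shifted upward with 0 of 30 members past the threshold and 4 adjusted over the list alone. Among them, CCL3 differed by 1.55 ± 0.34 (adjusted p = 0.0607). All of these lists also passed with an estimated correlation, at adjusted p = 0.00699, 0.0034, 0.0034, 0.0234 and 0.0234 with an estimated correlation, in the order named.

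Further lists passed camera in the same comparison, and their calls were lost with an estimated correlation. Hodgkin and Reed-Sternberg cell genes had a median of 0.02, with CCL22 alone of 20 past the threshold on either adjustment (camera adjusted p = 0.0484, and adjusted p = 0.53 with an estimated correlation). NF-kappaB targets (median 0.09, 0 of 25 passed, 2 adjusted over the list alone) gave a camera adjusted p = 0.00365, and an adjusted p = 0.235 with an estimated correlation. JAK-STAT feedback and target genes (0.14, 0 of 15, 3 adjusted over the list alone) gave 0.00928, and an adjusted p = 0.374 with an estimated correlation. Among p53 targets CDKN1A, a cyclin-dependent kinase inhibitor gene, rose by 0.42 ± 0.07, and 3 rose and 1 fell of 18 adjusted over the list alone (0.00747, and an adjusted p = 0.148 with an estimated correlation). Stress genes of the unfolded protein and amino acid response were shifted upward (median 0.14, camera adjusted p = 0.00145) and cholesterol synthesis (-0.14, adjusted p = 0.0312) and heat shock genes (-0.10, adjusted p = 0.0248) downward, with 0 members past the threshold on either adjustment in limma. With an estimated correlation the adjusted p of these 3 lists was 0.148, 0.603 and 0.374. With the T cell score as a covariate the Hodgkin and Reed-Sternberg cell (-0.0894), NF-kappaB (-0.0669) and JAK-STAT (-0.126) lists turned downward, JAK-STAT past the threshold (camera adjusted p = 0.043), and with the monocyte and macrophage score heat shock genes turned upward (0.0284). Several of these shifts rested on single arrays. Cholesterol synthesis had a median of 0 without coculture replicate 14 (camera adjusted p = 0.609), and its call also ended without monoculture replicate 31 (-0.08, adjusted p = 0.293) or coculture replicate 17 (-0.10, 0.0839). Heat shock genes had a median of -0.02 without monoculture replicate 19 (adjusted p = 0.529), and the call also ended without coculture replicate 14, 17 or 29 (adjusted p = 0.097, 0.0587 and 0.0616). Hodgkin and Reed-Sternberg cell genes lost their call without any 1 of 13 arrays (adjusted p up to 0.338) and kept it only without monoculture replicate 31, coculture replicate 14 or 27, dexamethasone monoculture replicate 7 or 20 or dexamethasone coculture replicate 30, with medians between 0 and 0.133. Without monoculture replicate 12 the p53 and stress response calls ended (adjusted p = 0.0506 and 0.0717) and the NF-kappaB median was 0.06, and it was 0.05 without coculture replicate 21. Lists of erythrocyte and platelet markers (0.264), the B cell programme (0.416), MHC class II (0.337), glucocorticoid-induced genes (0.264), proliferation (0.092), hypoxia and glycolysis (0.624), immediate early genes (0.0732) and housekeeping genes (0.754) did not pass camera. For MHC class II and glucocorticoid-induced genes the median was below 0 (-0.00714 in each) while the mean and the test pointed upward.

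Transcripts of other cell types were present in the CD3-depleted cocultures. The T cell marker score was 6.96 ± 0.164 (SD, n = 7) in coculture and 6.61 ± 0.0106 (n = 3) in monoculture, a difference of 0.35 (exact permutation p = 0.0167, adjusted 0.0476). Of 25 T cell markers, CD2 passed over all probe sets and 17 adjusted over the list alone (camera adjusted p = 4.92e-19, and adjusted p = 0.0234 with an estimated correlation), while CD3D differed by 1.12 ± 0.24 (adjusted p = 0.0529), CD3E by 0.67 ± 0.14 (0.0568) and CD4 by 0.31 ± 0.09 (0.264). NK and cytotoxic cell markers had a median difference of 0.43, with 0 of 17 passed and 12 adjusted over the list alone, and an adjusted p = 0.0294 with an estimated correlation. Among these, GZMA differed by 1.69 ± 0.46 (adjusted p = 0.18) and NKG7 by 1.22 ± 0.29 (0.0983). T cell effector and activation genes gave a camera adjusted p of 0.000155, with 0 of 17 passed and 3 adjusted over the list alone, and an adjusted p = 0.0897 with an estimated correlation, and their median turned to -0.0823 with the T cell score as a covariate. The monocyte and macrophage score was 0.26 higher (exact permutation p = 0.0167, adjusted 0.0476), and LYZ was the only 1 of 15 members past the threshold on either adjustment (camera adjusted p = 0.00567, and adjusted p = 0.374 with an estimated correlation). Most of that score difference came from LYZ, and the median over the members was 0.10, with 12 above 0 and 3 below. These exact p-values were the smallest that 7 against 3 arrays allow.

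**Figure D2:**
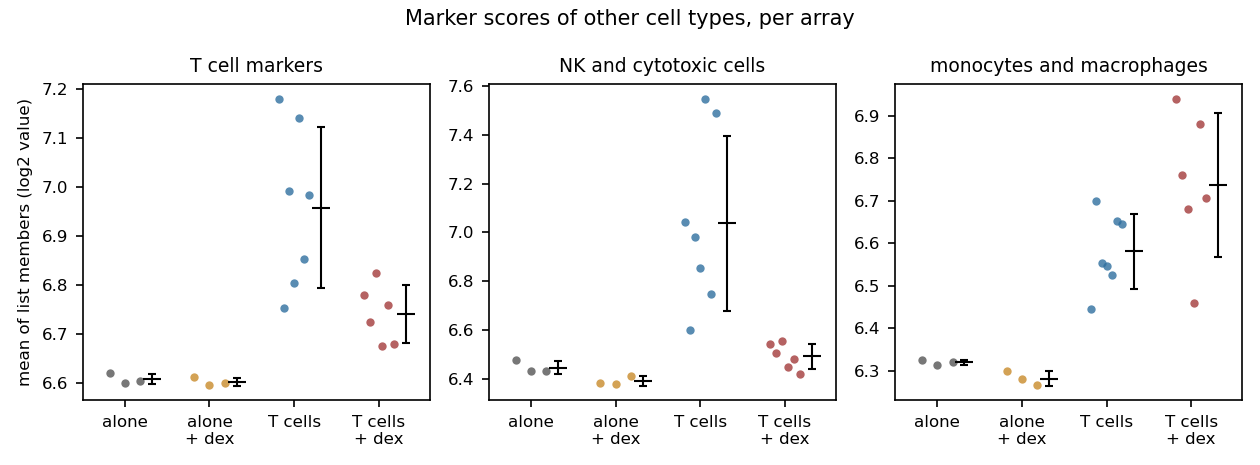
Mean log2 value of 25 T cell, 17 NK and cytotoxic cell and 15 monocyte and macrophage markers on each array (points), with the mean ± SD of each group (black, n = 3, 3, 7 and 6). T cell and NK scores were lower in coculture with dexamethasone than without (6.74 against 6.96, and 6.49 against 7.04), whereas the monocyte and macrophage score was 6.74 against 6.58.

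Dexamethasone changed 71 probe sets in L428 cells cultured alone. TBCEL (7944623) rose most, from 7.17 ± 0.115 to 9.77 ± 0.451 (SD, n = 3 each), a difference of 2.60 ± 0.32 log2 (limma adjusted p = 0.00131). PRDM1, the transcription factor gene of plasma cell differentiation, rose by 1.50 ± 0.19, the B cell kinase gene BLK by 1.53 ± 0.17, and the p53 target and stress sensor gene SESN1 by 1.43 ± 0.11 (adjusted p = 3.6e-06). ZP2 (1.70 ± 0.22), CHMP2B (1.37 ± 0.14), ANKS4B (1.33 ± 0.19), GSTM2 (1.07 ± 0.21), TIGD2 (1.03 ± 0.17) and OGFRL1 (1.0 ± 0.15) completed the largest rises. FANK1 (-0.87 ± 0.12), DENND5A (-0.63 ± 0.09), FCER2, which encodes the low-affinity IgE receptor CD23 (-0.57 ± 0.10), STRBP (-0.57 ± 0.10), CEMIP2 (-0.53 ± 0.10), SGPL1 (-0.53 ± 0.10), the B cell transcription factor gene BACH2 (-0.47 ± 0.08) and PREX1 (-0.40 ± 0.08) fell. Of the 71, 61 were higher and 10 lower. TSC22D3, the glucocorticoid-induced leucine zipper gene, differed by 1.50 ± 0.32 without passing (adjusted p = 0.069), and PER1 (0.07 ± 0.11) and the receptor gene NR3C1 (0.00 ± 0.13) did not pass either. CCL22 (-0.10 ± 0.53), CD274 (-0.23 ± 0.16), CCL17 (0.00 ± 0.42) and TNFRSF8 (0.03 ± 0.11) showed no difference past the threshold. These errors come from 1 spread per gene over all 19 arrays, cocultures included. Within the monocultures CCL22 had SDs of 0.153 without and 0.115 with dexamethasone. CD274 was 6.9 on all 3 arrays without dexamethasone and 6.6 to 6.7 with it. Leaving out monoculture replicate 12, 19 or 31 gave 29, 31 or 29 probe sets, and leaving out replicate 7, 20 or 32 of the dexamethasone arrays gave 46, 43 or 28. When only these 6 arrays were fitted, 0 passed in limma and 2301 had an unadjusted p under 0.05.

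Of 24 gene lists, 3 shifted with dexamethasone in monoculture. Proliferation genes were shifted upward (median 0.17, 26 of 29 above 0), with CDK1 at 0.23 ± 0.12 and MCM6 at 0.30 ± 0.14, and interferon gamma response genes (-0.10) and cytokines and chemokines (-0.03) downward, at camera adjusted p = 0.00108, 0.0328 and 0.0328. Housekeeping genes differed in the same direction as proliferation genes without passing (10 of 11 above 0, mean 0.12 against 0.14, camera adjusted p = 0.0839). The call was lost for all 3, at adjusted p = 0.808, 0.808 and 0.659 with an estimated correlation, and none of their members passed over all probe sets in limma. Among the interferon gamma genes, GBP4 was 7.73 ± 0.208 (SD, n = 3) without and 7.07 ± 0.208 (n = 3) with dexamethasone. GBP5 was 8.33 ± 0.115 without and 7.50 ± 0.1 with it. Adjusted over the list alone, 2 cytokine genes were lower, with CSF1 at -0.57 ± 0.12 (adjusted p = 0.0526) and IL5 at -0.97 ± 0.22 (0.0948) over all probe sets. Of 28 glucocorticoid-induced genes, BCL2L11, which encodes the pro-apoptotic protein BIM, rose by 0.57 ± 0.10 (adjusted p = 0.0137), and 4 rose adjusted over the list alone. That list did not pass camera (adjusted p = 0.176), and its median of -0.03 differed in sign from its mean of 0.12 and from the test. BLK was the 1 of 18 B cell programme genes and SESN1 the 1 of 18 p53 targets that rose on either adjustment, at camera adjusted p = 0.144 and 0.258. The 3 lists became 6 after quantile normalization, 10 when only these 6 arrays were fitted, 7 without arrays 14 and 15 (chosen after the data were seen), and 1 without monoculture replicate 19 or dexamethasone replicate 7. The interferon gamma call ended without monoculture replicate 19 or 31 or dexamethasone replicate 7 or 20 (adjusted p = 0.0665, 0.0629, 0.104 and 0.0674), and the cytokine call without monoculture replicate 12 or 19 or dexamethasone replicate 7 or 32 (0.0747, 0.0665, 0.0855 and 0.0649). The B cell list had a median of -0.07 and a test pointing downward with a mean of 0.01. The largest difference among the 5 scores of other cell types was -0.0608, for T cell effector genes, and the smallest exact permutation p was 0.1, the lowest that 3 against 3 arrays allow.

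In coculture, dexamethasone lowered CCL22, CXCL10, MX1 and the granzyme genes GZMA and GZMB, and raised TBCEL, ZP2, PRDM1 and BLK, which it had raised in monoculture. CCL22 fell from 9.17 ± 1.08 (SD, n = 7) to 6.85 ± 0.152 (n = 6), a difference of -2.32 ± 0.36 log2 (limma adjusted p = 0.0028). GZMA (-1.71 ± 0.37), GZMB (-1.54 ± 0.33) and NKG7 (-1.20 ± 0.23), products of cytotoxic lymphocytes, fell together with CD52 (-1.49 ± 0.28), MX1 (-1.30 ± 0.25), ARHGDIB (-1.27 ± 0.28), the histone gene H3C11 (-1.20 ± 0.27), SLC26A4 (-1.18 ± 0.18) and the interferon-induced chemokine gene CXCL10 (-1.14 ± 0.23). CD274 fell by 0.63 ± 0.11 (adjusted p = 0.0056). TBCEL rose by 1.94 ± 0.22 (adjusted p = 0.000196), followed by ZP2 (1.32 ± 0.15), TRIB1 (1.12 ± 0.16), PRDM1 (1.07 ± 0.13), BLK (1.06 ± 0.12), TSC22D3 (0.98 ± 0.22, adjusted p = 0.0331), ANKS4B (0.97 ± 0.13), the macrophage mannose receptor gene MRC1 (0.95 ± 0.21), TOX2 (0.95 ± 0.16) and KIF13B (0.92 ± 0.10). PER1 (-0.06 ± 0.08), NR3C1 (0.05 ± 0.09), CCL17 (-0.46 ± 0.28) and TNFRSF8 (0.02 ± 0.07) did not pass. The CCL17 difference was -0.19 without dexamethasone replicate 15, -0.68 without coculture replicate 14 and -0.41 without both, where it passed (adjusted p = 0.0256, against 0.17 to 1 in the other alternatives). It ran from -0.175 to 0.169 with marker scores as covariates. The T cell and NK marker scores differed by -0.217 and -0.546 between these groups. In total 169 probe sets were higher and 203 lower, against 225 and 202 after quantile normalization. The 372 became 576 without coculture replicate 14, which held several dexamethasone-raised genes above the other cocultures, and 238, 237 or 241 without coculture replicate 25 or replicate 8 or 30 of the dexamethasone arrays. With the T cell marker score as a covariate 22 passed, with the monocyte and macrophage score 112, and with the T cell, NK and monocyte scores together 1, where the difference of GZMA turned to 0.0304.

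Of 24 lists, 15 shifted with dexamethasone in coculture, 14 of them downward, but the ligand list was the only 1 to pass with an estimated correlation as well. In that list of costimulation, checkpoint and adhesion ligands, CD274, CD80 (-0.47 ± 0.08), TNFSF10 (-0.54 ± 0.10) and PDCD1LG2, which encodes PD-L2 (-0.41 ± 0.10), fell among 31 members, and 5 adjusted over the list alone (camera adjusted p = 3.97e-06, and adjusted p = 0.0201 with an estimated correlation). Type I interferon genes had a median of -0.53, with 10 of 28 lower and 25 adjusted over the list alone, including IFI6 (-0.87 ± 0.16) and IFIH1 (-0.47 ± 0.08), on arrays whose T cell score differed by -0.217. Interferon gamma response genes had a median of -0.43 (-0.28 without dexamethasone replicate 22), with 5 of 15 lower and 10 adjusted over the list alone, including GBP4 (-1.12 ± 0.20), GBP5 (-1.04 ± 0.17) and GBP2 (-0.99 ± 0.16). The camera adjusted p was 3.87e-24 and 7.23e-10, and the calls were lost at adjusted p = 0.057 and 0.0535 with an estimated correlation. GBP4 and GBP5 were also lower with dexamethasone in monoculture, without passing. Of 20 Hodgkin and Reed-Sternberg cell genes 6 fell, or 10 adjusted over the list alone, with TNFRSF9 at -0.67 ± 0.09, ID2 at -0.82 ± 0.14 and a median of -0.36, or -0.21 without dexamethasone replicate 15 (6.72e-10, and adjusted p = 0.057 with an estimated correlation). Of 30 cytokines and chemokines, IL5 (-0.86 ± 0.15), IL13 (-1.01 ± 0.22) and TNFSF13B (-0.24 ± 0.05) fell, while 11 were lower and 1 higher adjusted over the list alone (0.000165, and adjusted p = 0.0535 with an estimated correlation). IL6 fell by 0.96 ± 0.13 as the 1 of 25 NF-kappaB targets that passed, with 10 lower and 1 higher adjusted over the list alone (4.97e-06, and adjusted p = 0.0623 with an estimated correlation). STAT3 fell by 0.55 ± 0.10 as the 1 of 15 JAK-STAT genes, with 6 adjusted over the list alone (5.63e-06, and adjusted p = 0.113 with an estimated correlation).

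MHC class I genes (median -0.17), the unfolded protein and amino acid stress response (-0.14) and heat shock genes (-0.11) were shifted downward by dexamethasone in coculture at camera adjusted p = 0.00165, 0.000479 and 0.0248, with 0 members past the threshold on either adjustment in limma and adjusted p = 0.113, 0.113 and 0.36 with an estimated correlation. The heat shock call ended without coculture replicate 6, 21 or 27 or dexamethasone replicate 8 or 15 (camera adjusted p = 0.0853, 0.0547, 0.0528, 0.112 and 0.12), and the MHC class I median was -0.10 without dexamethasone replicate 22. The p53 targets were shifted downward (median -0.07, camera adjusted p = 0.0372, and adjusted p = 0.225 with an estimated correlation), although SESN1 rose by 0.55 ± 0.07 and, adjusted over the list alone, 6 of 18 were lower and 1 higher. The p53 call ended without coculture replicate 14, 25 or 29 or dexamethasone replicate 18 or 22 (adjusted p = 0.0894, 0.0553, 0.0501, 0.0956 and 0.118). Of the glucocorticoid-induced genes, TSC22D3, BCL2L11 (0.32 ± 0.07) and PIK3IP1 (0.30 ± 0.07) rose among 28, and 3 were higher and 2 lower adjusted over the list alone, without a shift of the list (camera adjusted p = 0.109). Proliferation genes did not shift in coculture (median 0.02, camera adjusted p = 0.75). For the B cell programme (0.843) and the erythrocyte and platelet markers (0.843), the median was below 0 and the test pointed upward.

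The markers of other cell types moved apart with dexamethasone in coculture. The T cell score differed by -0.217 (6.74 ± 0.0583, n = 6, against 6.96 ± 0.164, n = 7, exact permutation p = 0.00932, adjusted 0.0476), and the NK and cytotoxic score by -0.546 (exact permutation p = 0.00117, the smallest possible, adjusted 0.0233). Of 25 T cell markers CD2 (-1.01 ± 0.22), CD96 (-0.62 ± 0.13) and CD247 (-0.26 ± 0.06) fell and 12 were lower adjusted over the list alone. Of 17 NK and cytotoxic markers 5 fell, among them CST7 (-0.57 ± 0.11), and 12 adjusted over the list alone. T cell effector genes were lower as a list, with 0 of 17 passed and 8 adjusted over the list alone. The camera adjusted p of these lists was 2.47e-08, 1.72e-10 and 1.72e-06, and the calls were lost at adjusted p = 0.113, 0.0603 and 0.057 with an estimated correlation. In contrast, CD163, a scavenger receptor gene of macrophages, rose by 0.84 ± 0.14, VSIG4 by 0.30 ± 0.05 and CD14 by 0.26 ± 0.05 among 15 monocyte and macrophage markers, 5 of which were higher adjusted over the list alone (camera adjusted p = 1.15e-05, and adjusted p = 0.113 with an estimated correlation). The monocyte and macrophage score differed by 0.156 without passing (exact permutation p = 0.0641, adjusted 0.0916), and LYZ was 8.97 ± 0.9 with dexamethasone and 8.90 ± 0.852 without.

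**Figure D3:**
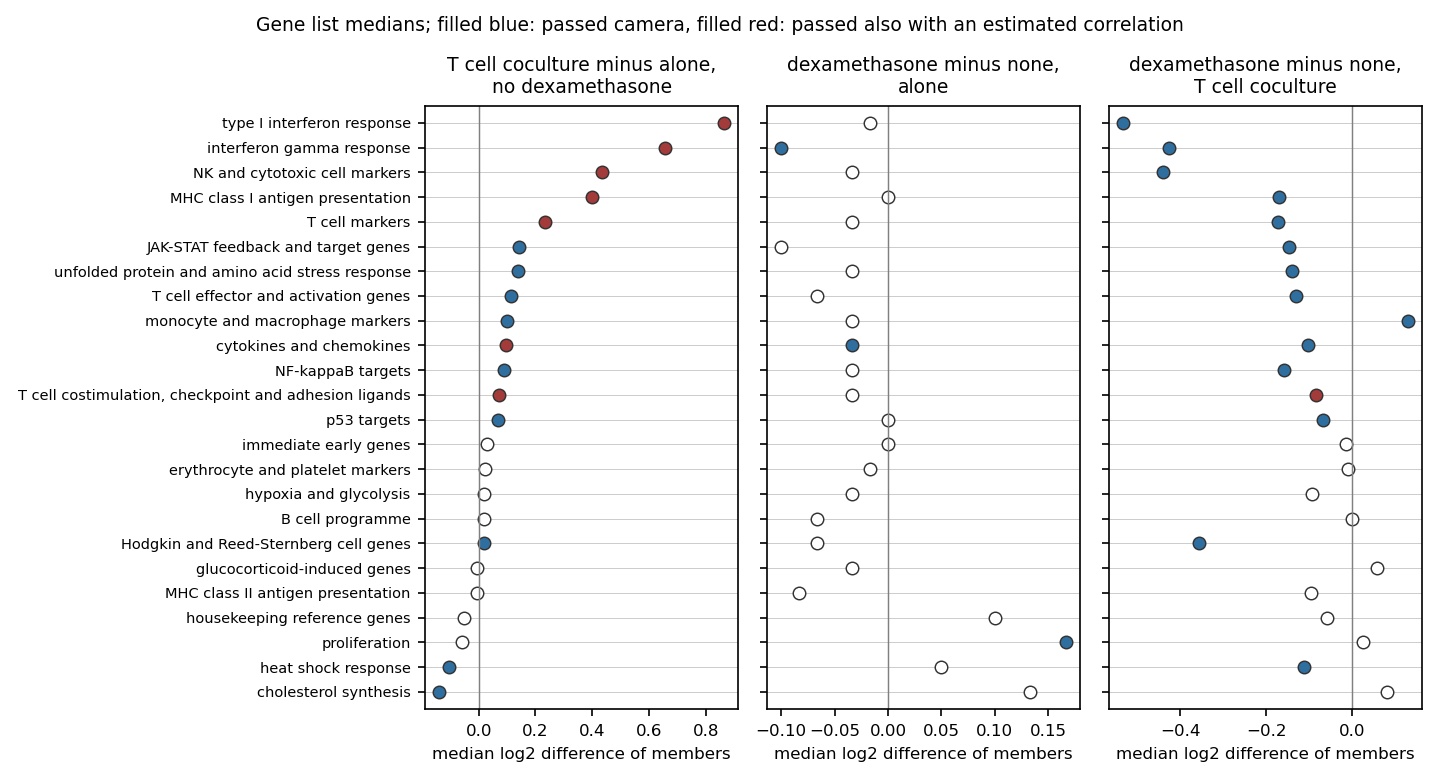
Median log2 difference of the measured members of 24 gene lists (points) for coculture against L428 cells alone without dexamethasone, and for dexamethasone against none in cells alone and in coculture. The horizontal scales differ between panels, and filled points passed camera (16, 3 and 15 lists), of which 7, 0 and 1 (red) passed with an estimated correlation too.

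The dexamethasone effects in monoculture and in coculture, which share no arrays, had 44 raised and 6 lowered probe sets in common, against 0.319 and 0.0628 for independent lists of these sizes. TBCEL, ZP2, PRDM1, BLK, ANKS4B and SESN1 were among the raised genes. Across all 32321 probe sets, which are not independent replicates, the effects had a Pearson correlation of 0.207 and a Spearman correlation of -0.0462, and 37.4% had the same sign. The SE of the Pearson correlation from leaving out each array was 0.188, with a range of 0.119 to 0.272. A difference of exactly 0 in only 1 culture, which values of 1 decimal allow, counted as unlike. The remaining probe sets are therefore not all of opposite sign. Among the 393 probe sets that passed in either culture the Pearson correlation was 0.795, and for the 71 that passed in monoculture it was 0.925. Both sets were chosen by these same effects, so these correlations are descriptive only.

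**Figure D4:**
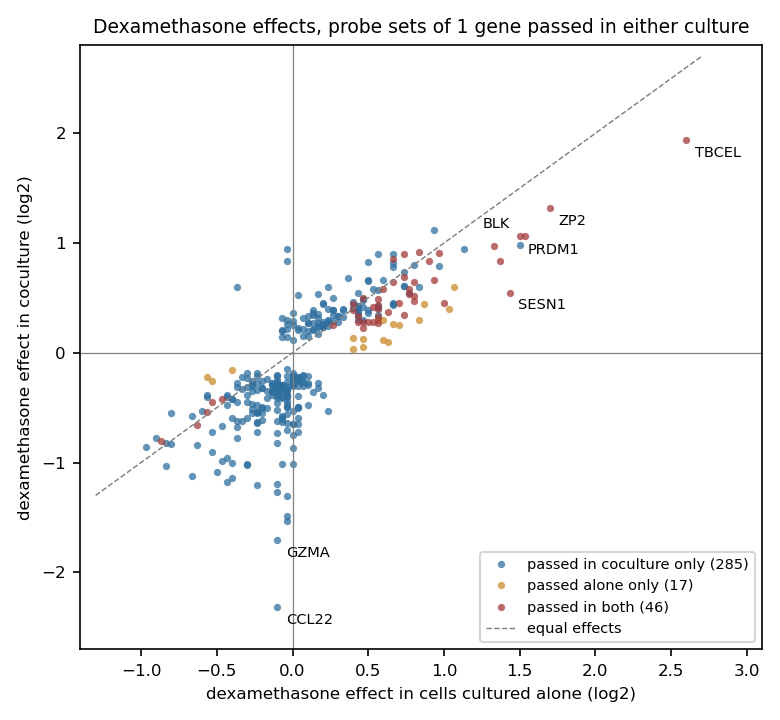
Dexamethasone effect (log2) in L428 cells alone (horizontal) and in T cell coculture (vertical) for the 348 probe sets of 1 gene that passed in either, coloured by where they passed, with the line of equal effects (dashed). Of these, 46 passed in both cultures, and CCL22 lay at -0.10 in cells alone and -2.32 in coculture.

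When both cultures contained dexamethasone, 5 probe sets passed between coculture and monoculture. SESN1 was 7.63 ± 0.197 (SD, n = 6) in coculture and 8.57 ± 0.153 (n = 3) in monoculture, a difference of -0.93 ± 0.09 log2 (limma adjusted p = 0.000151). The epithelial keratin gene KRT5 (-0.48 ± 0.06) and GREB1 (-0.40 ± 0.04) were lower as well, and VSIG4, a macrophage complement receptor gene, was 0.45 ± 0.07 higher (adjusted p = 0.0239). With 1 unnamed probe set, 1 was higher and 4 lower, and 3948 had an unadjusted p under 0.05. LYZ differed by 2.87 ± 0.49 and GBP5 by 1.25 ± 0.22, both without passing (adjusted p = 0.05). CCL22 (0.22 ± 0.46), CD274 (0.33 ± 0.14), CCL17 (-0.58 ± 0.36, and -0.31 without coculture replicate 15), TNFRSF8 (0.12 ± 0.09), CD2 (0.50 ± 0.28), CD3D (0.35 ± 0.24), CD3E (0.23 ± 0.15) and CD4 (0.20 ± 0.10) did not pass. The CCL17 difference ran from -0.835 to 0.262 with marker scores as covariates. Without dexamethasone replicate 7 of the monocultures 3 passed, without replicate 22 of the cocultures 50 passed, and after centring each array on its median 7 were higher and 5 lower.

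Interferon and macrophage lists were shifted upward in that comparison, none of them with an estimated correlation. Type I interferon genes had a median of 0.38 with 7 of 28 higher adjusted over the list alone, and interferon gamma genes 0.35 with 8 of 15. MHC class I genes had a median of 0.24 with 3 of 14, and monocyte and macrophage markers 0.23 with 11 of 15. Cytokines and chemokines (0.08, with 4 of 30), T cell markers (0.12, with 0 of 25) and the B cell programme (0.08, with 2 of 18 lower) completed the upward shifts, all counts adjusted over the list alone. Camera adjusted p-values in this order were 1.57e-08, 5.53e-09, 0.00031, 5.77e-11, 0.00587, 0.00031 and 0.0256, and adjusted p = 0.375, 0.0987, 0.142, 0.0987, 0.122, 0.422 and 0.375 with an estimated correlation. Proliferation (-0.20), heat shock (-0.28), cholesterol synthesis (-0.15) and housekeeping genes (-0.17) were shifted downward at camera adjusted p = 1.85e-06, 1.85e-06, 0.00868 and 0.0107, and adjusted p = 0.395, 0.122, 0.644 and 0.422 with an estimated correlation. Of these 4 lists, heat shock genes had 6 of 10 members lower adjusted over the list alone, and the others had 0. Proliferation genes turned upward with the monocyte and macrophage score (0.0193) and with T cell, NK and monocyte scores as covariates (0.103, camera adjusted p = 0.0188, past the threshold), and the B cell programme turned downward by camera in these fits (medians 0.0209 and -0.0225). Without coculture replicate 15 the calls of cholesterol synthesis (-0.06, camera adjusted p = 0.0997) and housekeeping genes (-0.13, adjusted p = 0.0746) ended. The cholesterol call also ended without monoculture replicate 7 (-0.10, adjusted p = 0.054), and the B cell call without monoculture replicate 20 or coculture replicate 8 (adjusted p = 0.0639 and 0.0512). The T cell score was 0.138 higher (exact permutation p = 0.0238, n = 6 and 3, adjusted 0.0476) and the monocyte and macrophage score 0.456 higher (exact permutation p = 0.0238, adjusted 0.0476), the smallest p that 6 against 3 arrays allow. The NK and cytotoxic score was 0.101 and the erythrocyte and platelet score 0.0833 higher, with the same exact and adjusted p. The T cell effector score was 0.0529 higher without passing (exact permutation p = 0.0476, adjusted 0.0733).

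The difference between the dexamethasone effects in coculture and in monoculture reached the threshold for 0 probe sets in limma, with 2385 at an unadjusted p under 0.05. SESN1 came closest, at -0.89 ± 0.13 log2 and an adjusted p of 0.07, and passed when the test was limited to the brighter probe sets (adjusted p = 0.0423) or to 1 probe set per gene (0.033). Over the alternatives its adjusted p ran from 0.00903 to 0.525. CCL22 had an interaction of -2.22 ± 0.64 (adjusted p = 0.577) and CD274 of -0.40 ± 0.19 (0.675), so a larger fall in coculture than in monoculture was not established for either. In monoculture CCL22 was 6.73 without and 6.63 with dexamethasone, near the table median of 6.6, where a fall may not show. Type I interferon genes had the strongest list interaction (median -0.47, 0 of 28 passed in limma on either adjustment, camera adjusted p = 1.72e-12), which was lost at an adjusted p = 0.431 with an estimated correlation. Without dexamethasone replicate 32 of the monocultures, or replicate 18 or 30 of the cocultures with dexamethasone, 1 probe set passed.

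Of the 85 probe sets raised by coculture without dexamethasone, 49 were lowered and 0 raised by dexamethasone in coculture, and 83 had a negative difference. Their median coculture effect was 0.73 without and 0.32 with dexamethasone. These comparisons share the 7 coculture arrays, which alone pushes their effects in opposite directions. When the 7 coculture arrays were divided between the comparisons in all 70 ways of 3 against 4, the overlap had a median of 6.5 and ranged from 0 to 23, with medians of 61 and 121.5 probe sets called. In these divisions a median of 95.2% of the raised probe sets had a negative difference (lowest 50%), against 97.6% with all arrays. Over all probe sets the correlation of the effects was -0.475, against -0.373 in 50 simulations without effects, and the covariance -0.00655 against -0.00285.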

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

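The tests of monocyte and macrophage RNA behind the interferon and CCL22 patterns, and that of array level, were chosen after the results were seen, and the others before. In 12 of 122 groups of 6 or 7 values examined, 1 array lay far from the rest of its group, which chance alone gives in about 1 of 20 groups of unrounded values. The deposited values have 1 decimal, so this rate is only a rough guide here.

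Coculture replicate 14 stood apart for 5 genes. In this array TBCEL was 8.5 (7 to 7.4 in the other cocultures), ZP2 7.3 (6.3 to 6.4), KIF13B 7.5 (6.9 to 7.1), ANKS4B 6.8 (6.3 to 6.5) and CCL17 10.6 (11.9 to 12.3). CCL17 was also low in dexamethasone coculture replicate 15, at 10.1 (11.5 to 12). Single arrays also stood apart for ZP2 at 7.3 (7.8 to 8) and CNTN1 at 7.4 (6.8 to 7) in dexamethasone coculture replicate 22, and for DENND5A at 8.4 (8.1 to 8.2) in dexamethasone coculture replicate 18. In coculture replicate 27 GBP5 was 9.2 (9.7 to 10). DNER at 6.7 in coculture replicate 27 (6.6 in all others) and KRT5 at 6.5 in coculture replicate 21 (6.4 in all others) differed by 1 rounding step from tied values, which says nothing about their spread.

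For 12 lists the dexamethasone effect in coculture differed from that in monoculture by camera, although each call was lost with an estimated correlation, at adjusted p = 0.431 for 11 of them and 0.548 for proliferation. The median interaction was -0.47 for type I interferon response genes, -0.362 for NK and cytotoxic cell markers, -0.224 for interferon gamma response genes, -0.22 for Hodgkin and Reed-Sternberg cell genes and -0.157 for T cell markers. It was -0.171 for NF-kappaB targets, -0.17 for heat shock genes, -0.169 for proliferation genes, -0.168 for MHC class I genes, -0.164 for the unfolded protein and amino acid stress response and -0.1 for p53 targets. Monocyte and macrophage markers had a median interaction of 0.14, or 0.215 without dexamethasone coculture replicate 22. Leaving out 1 array ended the camera call for interferon gamma genes (monoculture replicate 12, dexamethasone monoculture replicate 32, coculture replicate 17, dexamethasone coculture replicate 22 or 30, adjusted p up to 0.0979) and MHC class I genes (replicate 12, 20, 21, 8 or 22 of these groups, up to 0.163). It also ended the call for proliferation genes (replicate 12, 20 or 15, up to 0.0699), the stress response (replicate 12, 20 or 8, up to 0.163) and heat shock genes (replicate 12 or 20, up to 0.118). Medians over these fits ran from -0.343 to -0.152 for interferon gamma genes (lowest without dexamethasone coculture replicate 18), -0.21 to -0.0655 for MHC class I genes, -0.221 to -0.107 for proliferation genes, -0.211 to -0.0738 for the stress response, -0.286 to -0.113 for heat shock genes (lowest without monoculture replicate 19) and -0.268 to -0.127 for Hodgkin and Reed-Sternberg cell genes (highest without dexamethasone coculture replicate 15). Of 100 relabellings of dexamethasone within the cultures, 9 including the real one gave as many probe sets at an unadjusted p under 0.05 (2385, highest other 3661). Relabelling each culture separately can turn a dexamethasone effect shared by both into a difference between them. These counts therefore do not measure chance alone, and chance was not excluded for the interaction.

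Interferon-response genes were higher in coculture, and residual T cell RNA was tested as a technical explanation. With the T cell marker score as a covariate, the median effect of the 43 pooled interferon genes was 0.84 against 0.85 without it. This was 99.5% of its size (70.2% to 115% leaving out each array), and the median effect was 0.76 with the monocyte and macrophage score. The medians of the SEs of these single genes were 0.258, 0.164 and 0.221 in that order, and no SE of the median effect was computed. Both scores hardly varied in monoculture (T cell score range 0.024, monocyte and macrophage score SD 0.00667 without dexamethasone), so the slopes came from the coculture arrays. Over the 7 cocultures the pooled interferon score correlated with the T cell score at -0.139 (exact permutation p = 0.749). Without the 2 arrays farthest on the T cell score the correlation was 0.296. These fits therefore cannot decide whether the amount of either RNA contributes. The calls of single interferon genes were not kept under these covariates, where the median of their SEs was wider. If the amount of monocyte and macrophage RNA were the source, its score should fall along with the interferon genes. With dexamethasone in coculture that score changed by 0.156 (SE 0.0767) while the pooled interferon score changed by -0.513 (SE 0.126). This cannot decide the question, since members of the score such as CD163 and VSIG4 rose with dexamethasone, while LYZ changed by 0.0667 (SE 0.489). A response of L428 cells to the T cells remains a hypothesis, and a change of activity within carried-over cells may contribute and was not tested.

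CCL22 was higher in coculture and lower with dexamethasone. Over the 7 cocultures its correlation with the T cell score was 0.162 (exact permutation p = 0.716, Spearman 0.214, and 0.104 without the 2 arrays farthest on the score), and so few arrays leave open whether the amount of T cell RNA contributes. With that score as a covariate the coculture effect was 2.13 (SE 0.71) against 2.44 (SE 0.446), and the call ended with a smaller effect and a wider standard error. The amount of monocyte and macrophage RNA as the source would need LYZ to fall with CCL22. With dexamethasone LYZ changed by 0.0667 (SE 0.489) while CCL22 changed by -2.32. This cannot decide the question, since LYZ is 1 gene with a wide error. Dexamethasone may also change it within such cells, as other macrophage genes such as CD163 and VSIG4 rose. Lower CCL22 transcription within carried-over macrophages remains possible, as does a response of the L428 cells, and neither was tested.

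Monocyte and macrophage genes were present in the cocultures, without dexamethasone mainly LYZ, and carried-over cells of that type are a candidate explanation. LYZ correlated with the mean of the other 14 markers over the 13 coculture arrays centred within groups (r = 0.644, permutation p = 0.0262, and Spearman 0.572, permutation p = 0.0548, past the threshold only for the former), with 0.269 within coculture, 0.901 within coculture with dexamethasone and 0.423 without the 2 farthest arrays, so the relation rests partly on those arrays. Array level was argued against, since array medians differed by 0.0308 (SE 0.0133) between coculture and monoculture and the marker score by 0.353. No biological explanation for their level was tested.

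Other divisions of the same arrays gave fewer calls for coculture without dexamethasone (93 probe sets, highest other 56, with 1 of 100 divisions, the real one, reaching that count) and for dexamethasone in coculture (372, highest other 19, again 1 of 100), a share under 0.05 for both. The divisions treat the arrays as independent replicates, which the labels do not establish, so they cannot exclude chance differences between cultures or donors. For coculture with dexamethasone, 2 of 84 divisions reached the 5 probe sets (highest other 8), a share under 0.05. For dexamethasone in monoculture the 10 possible divisions are too few for such a share (71, highest other 0, with 1 division reaching that count).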

How the results depend on the processing

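The fits without arrays 14 and 15, with the monocyte and macrophage score or with T cell, NK and monocyte scores as covariates, and without the probe sets numbered below the lowest named one were chosen after the data were seen, and the others before. No paired analysis was run, because the groups share no sample numbers and the labels name no pairs. Runs of consecutive numbers, which gave a correlation of 0.132, served as a block. Replicates 17 and 18 shared a run with replicates 19 to 22, so the block did not set replicates 14, 15, 17 and 18 apart. Unless a reason is given, the cause was not tested.

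Of 98 named gene results past the threshold, 95 kept their direction and call with a trended robust prior, 90 after quantile normalization, 88 after centring, 98 with array weights, 98 with runs of sample numbers as a block, 37 when only the arrays of the groups compared were fitted, 24 with the T cell score, 43 with the monocyte and macrophage score and 15 with 3 scores as covariates. Leaving out 1 array, between 62 and 94 did. Of 57 list shifts, 45 kept direction and call after quantile normalization, 55 after centring, 8 with an estimated correlation, 32 with the T cell score, 39 with the monocyte and macrophage score and 17 with 3 scores. Signal near the lowest values of the table limits what can be seen for dim genes.

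For coculture with dexamethasone, the 5 probe sets (1 higher, 4 lower) became 13 with a trended robust prior (8 and 5), 8 after quantile normalization (3 and 5), 12 after centring (7 and 5), 10 among bright probe sets (8 and 2), 8 with 1 probe set per gene (5 and 3), 12 with array weights (8 and 4), 21 with the block (12 and 9) and 12 without the low-numbered probe sets (9 and 3), the filters by testing fewer probe sets. Quantile normalization also gave 1 interaction probe set and 6 lists for dexamethasone in monoculture against 3, and 225 higher and 202 lower probe sets for dexamethasone in coculture. The bright filter and 1 probe set per gene each gave 1 interaction probe set. In the other alternatives, single arrays left out aside, limma gave 0 for the interaction, with 1281 to 2892 at an unadjusted p under 0.05.

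Fitting only the groups compared, with fewer arrays for the spread, gave 16 probe sets for coculture against 93, 0 for dexamethasone in monoculture against 71 (limma, 2301 at an unadjusted p under 0.05) with 10 lists, 226 for dexamethasone in coculture (117 higher and 109 lower) against 372 (169 and 203), and 0 for coculture with dexamethasone (limma, 4051 at an unadjusted p under 0.05). Array weights gave 146 for coculture and 118 for dexamethasone in monoculture. A minimum of 1 log2 left 27, 13 and 25 probe sets for coculture and for dexamethasone in monoculture and in coculture, and 0 for coculture with dexamethasone (limma, 3948 at an unadjusted p under 0.05). With an estimated correlation camera passed 7 lists for coculture, 0 for dexamethasone in monoculture, 1 for dexamethasone in coculture, 0 for coculture with dexamethasone and 0 for the interaction. Without arrays 14 and 15, 7 lists passed for dexamethasone in monoculture. The correlation of the dexamethasone effects was 0.795 among probe sets past the threshold, which were chosen by these effects, against 0.207 among all.

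With the T cell score as a covariate, 0 probe sets passed for coculture (limma, 1723 at an unadjusted p under 0.05) and 22 for dexamethasone in coculture, with 10 lists for coculture, 9 for dexamethasone in coculture and 5 for the interaction. With the monocyte and macrophage score the counts were 2 for coculture, 112 for dexamethasone in coculture and 1 for coculture with dexamethasone, with 6 lists for the latter and 6 for the interaction. With 3 scores they were 0 (limma, 1968 at an unadjusted p under 0.05), 1 and 0 (limma, 1567 at an unadjusted p under 0.05), with 8, 7 and 4 lists in these comparisons and 2 for the interaction. The scores differ between the cultures, which widens the errors of the coculture effects.

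Some directions reversed. After quantile normalization the interaction of proliferation genes turned upward by camera (median -0.00357). With the T cell score, the coculture medians became -0.031 for T cell markers, -0.0823 for T cell effector genes, -0.0894 for Hodgkin and Reed-Sternberg cell genes, -0.0669 for NF-kappaB targets and -0.126 for JAK-STAT genes (past the threshold, camera adjusted p = 0.043), and T cell markers became 0.00966 for dexamethasone in coculture and 0.033 for the interaction. With the monocyte and macrophage score, coculture medians became -0.0704 for its own markers and 0.0284 for heat shock genes, and with dexamethasone -0.0168 for its own markers, 0.0209 for B cell genes and 0.0193 for proliferation genes. With 3 scores, coculture medians became -0.0616 for T cell markers, 0.0251 for T cell effector genes, -0.106 for monocyte and macrophage markers, -0.0753 for Hodgkin and Reed-Sternberg cell genes, -0.108 for JAK-STAT genes and -0.0329 for heat shock genes. For dexamethasone in coculture they were -0.00753 for T cell and -0.00412 for NK markers, with GZMA at 0.0304. With dexamethasone, coculture medians were -0.0201 for monocyte and macrophage markers, -0.0225 for B cell and 0.103 for proliferation genes (past the threshold, camera adjusted p = 0.0188), and interactions were 0.0289 for T cell and -0.0051 for NK markers. A median can keep its sign where camera's direction turned, and a list under its own score is removed by construction.

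Leaving out each array gave 2 to 140 probe sets for coculture (2, 11 and 9 without monoculture replicates 12, 19 and 31, 55 and 140 without coculture replicates 17 and 27), 28 to 85 for dexamethasone in monoculture (29, 31 and 29 without monoculture replicates 12, 19 and 31, 46, 43 and 28 without dexamethasone replicates 7, 20 and 32), 237 to 576 for dexamethasone in coculture (576 and 238 without coculture replicates 14 and 25, 237 and 241 without dexamethasone replicates 8 and 30), 3 to 50 for coculture with dexamethasone (3 and 50 without replicates 7 and 22) and 0 to 1 for the interaction (limma, 1 without replicates 32, 18 or 30, and 2385 at an unadjusted p under 0.05 with every array). Lists passed ranged from 13 to 17, 1 to 3 (1 without monoculture replicate 19 or dexamethasone replicate 7), 14 to 16, 9 to 12 and 8 to 16 in the same order. The T cell score difference was 0.313 to 0.384 for coculture and 0.121 to 0.151 for coculture with dexamethasone, where without 1 monoculture array the smallest possible exact p is 0.0556 and 0.0714. It was -0.01 to 0.000667 and -0.251 to -0.18 for dexamethasone in monoculture and coculture, and the correlation of effects was 0.119 to 0.272.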

Other observations

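All tests in this part were chosen after the results were seen. The 61 probe sets that dexamethasone raised in monoculture, picked by that difference, had a mean of 7.71 ± 0.00413 (SD, n = 3) without and 8.50 ± 0.0707 (n = 3) with dexamethasone. The choice came from the fit of all 19 arrays, so the spread of the coculture arrays entered it, although their means did not enter the difference tested. On the coculture arrays the mean was 7.76 ± 0.0805 (n = 7) without and 8.27 ± 0.0797 (n = 6) with dexamethasone. Coculture replicate 14 had the highest value without dexamethasone, 7.89, and the other cocultures lay between 7.67 and 7.82.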
